A study of Mus musculus with 18 samples.

How the data were processed

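Liver RNA from 18 male C57BL6 mice was measured on a gene-level expression array, with 3 arrays in each of 6 groups. Per the labels' protocols, total RNA was extracted with Trizol and labelled with biotin, and the arrays of a group are biological replicates. The deposited table holds 1 value per probe and array for 34472 probes. The authors made these values with Transcriptome Analysis Console, per the submitters' processing notes, which give no version. The background correction, the normalization and the summarization of the probes are not given in the sources used here. The deposited values were taken as log2 signal because of their range and skew, although the labels do not name the base of the logarithm, so every log2 difference and fold below rests on that reading. The median signal per array lay between 4.43 and 4.59. The correlation of any 2 arrays lay between 0.9749 and 0.9913, and at most 1.83% of values were identical between 2 arrays. For arrays, their number limits the precision.

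Probes were assigned to genes by the table of probe annotations made for this series. There were 23521 probes with 1 gene symbol, 1814 with several and 9137 with none, and the probes with 1 symbol covered 22180 different symbols. The Entrez numbers of 23328 of these probes were present in the RefSeq table, and all 23328 had the same symbol there. All probes were tested, without a filter on signal. Where several probes measured 1 gene, the probe with the highest mean signal stood for the gene in the gene lists and in the genes named.

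Differences were computed with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to the 18 arrays, with 12 residual degrees of freedom and moderated variances (5.21 prior degrees of freedom), and 9 contrasts were tested. These were the high-fat against the low-fat control, each compound against the control of its diet, PFNA against PFOS within each diet, and the interaction of diet with each compound. The p-values were adjusted by the method of Benjamini and Hochberg within each contrast, and a probe was called at an adjusted p under 0.05. Errors beside log2 differences are the standard errors of this fit, with n = 3 arrays in each group compared, and intervals are 95% confidence intervals from its moderated t distribution. Positive values mean a higher signal in the first group named.

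The lists of genes, the tests of the 9 contrasts, the rule for naming genes and the alternative settings were fixed before the data were examined, apart from those said here or in the closing section to have been chosen later. For each contrast the rule took the 10 largest rises and the 10 largest falls among the called genes, leaving out predicted or unnamed gene models, small RNAs and immunoglobulin or T cell receptor segments. It also took up to 4 called members of each gene list, or the 2 members with the largest difference where no member was called. A gene named outside this rule is described as such where it appears.

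The 36 lists of genes were written from general knowledge and not chosen on these samples. They hold 602 different genes, of which 534 were measured by a probe of 1 gene and 32 belong to more than 1 list. The lists cover peroxisomal and mitochondrial fatty acid oxidation, other targets of PPARA, targets of CAR and PXR, NRF2 and AHR, fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, bile acids, lipid droplets, lipoproteins, transporters of foreign compounds, glucose metabolism, the urea cycle, complement and coagulation, the acute phase response, sex-biased liver genes, zonation, stress, cell cycle, p53 targets, interferon-stimulated genes, oxidative phosphorylation, the circadian clock, immediate-early genes, and markers of other cell types. The last group covers stellate cells, Kupffer cells, lymphocytes, neutrophils, endothelium, cholangiocytes, adipocytes, exocrine pancreas and erythroid cells. Each list was tested against all other probes with camera of limma at a preset correlation of 0.01 between genes, and the p-values were adjusted over the 36 lists of a contrast. The same test was repeated with the correlation estimated from the arrays, which widens the error of lists whose members vary together between animals. Members were counted as called from the adjustment over all probes and, separately, adjusted over the list alone.

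Overlaps were counted as probes called in both contrasts in the same direction. Contrasts that share their 3 control arrays are correlated without any effect, so the overlap, the correlation and the covariance were also computed in 100 simulated data sets without effects. The 3 control arrays cannot be split into 2 sets of at least 2 arrays, so part of any excess may come from the shared controls. The overlap of independent lists was computed from the numbers called and the number of probes tested.

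The scripts were tested on simulated data with 200 changed probes, in 5 simulations per contrast. A 2-fold change was recovered for 72.8% of probes in the contrast of diets, 78.2% in that of PFOS on the high-fat diet, 76.2% in that of PFNA with PFOS on the high-fat diet, and 44.4% in the interaction of diet with PFOS. A 4-fold change was recovered for 98.8%, 97.8%, 98.6% and 92.4% of probes. False calls made up 5.00%, 5.60%, 4.20% and 4.90% of the calls. A shifted gene list was called in 5 of 5 simulations of each of these contrasts, and the other lists in 0, 0, 1 and 0 of 175 tests. The simulated probes varied independently of each other. These list results therefore do not show how often the preset correlation calls lists whose members vary together between animals.

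The replicate numbers showed no general pairing of the arrays across groups. Among 45 pairs of arrays with the same number in different groups, the median correlation of deviations from the group means was −0.001, and 3 pairs were over 0.1. The highest was 0.421. Among 90 pairs with other numbers the median was 0.005, 2 pairs were over 0.1 and the highest was 0.224, so a link between single arrays is not excluded. For 8 of 18 arrays the closest array of another group had the same number. A fit with the replicate number as a block was therefore kept as an alternative. The other settings tried were quantile normalization, the share of 0.5 of the probes with the higher mean signal, a fit to the compared groups alone, a variance trend with robust moderation, an unadjusted p under 0.05 with a change of at least 2-fold, each array left out in turn, and for the lists the estimated correlation and the rotation test fry. Unlike camera, fry tests a list against no change and not against the other probes, so its calls answer a different question. Leaving out 2 arrays together, and leaving out each array in turn for the lists, were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. All 18 columns of values were used. Doses and preparation batches are not given in the sources used here.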

Results

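Liver RNA was measured in male C57BL6 mice that ate a low-fat diet (10% of energy from fat) or a high-fat diet (45% of energy from fat) for 12 weeks, from 6 to 18 weeks of age. Each diet was given alone or with 1 of 2 perfluorinated compounds. PFOS (perfluorooctane sulfonic acid) and PFNA (perfluorononanoic acid) carry the same number of fluorinated carbons and differ in their head group, which is a sulfonic acid in PFOS and a carboxylic acid in PFNA. The 6 groups were thus the control, PFOS and PFNA groups of each diet, with 3 biological replicates and 3 arrays per group. The median log2 signal per array lay between 4.43 and 4.59. The doses are not given in the sources used here. The title of the series names the effect of diet on fatty liver disease induced by these compounds, so the comparisons ask what each compound changed on each diet, whether the compounds differed and whether the diet altered the response.

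The first principal component of the 34472 probes held 17.9% of the variance and parted 5 arrays from the other 13. The 3 arrays of PFOS on the high-fat diet had scores of 27.8, 34.9 and 38.6. PFOS on the low-fat diet, replicate 3, had a score of 32.9, and PFNA on the high-fat diet, replicate 3, had a score of 32.4. The other 13 arrays, including the other replicates of those 2 groups, lay between −22.9 and −8.1. These 2 replicates are called the 2 divergent arrays below. The number of probes called in each contrast, the overlaps and the list tests were also computed without them. The response sizes, the probes called in every exposure and the small nucleolar RNAs were not. The 2 arrays were left out because of their values, after seeing the data, so the results without them are not independent evidence.

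**Figure D1:**
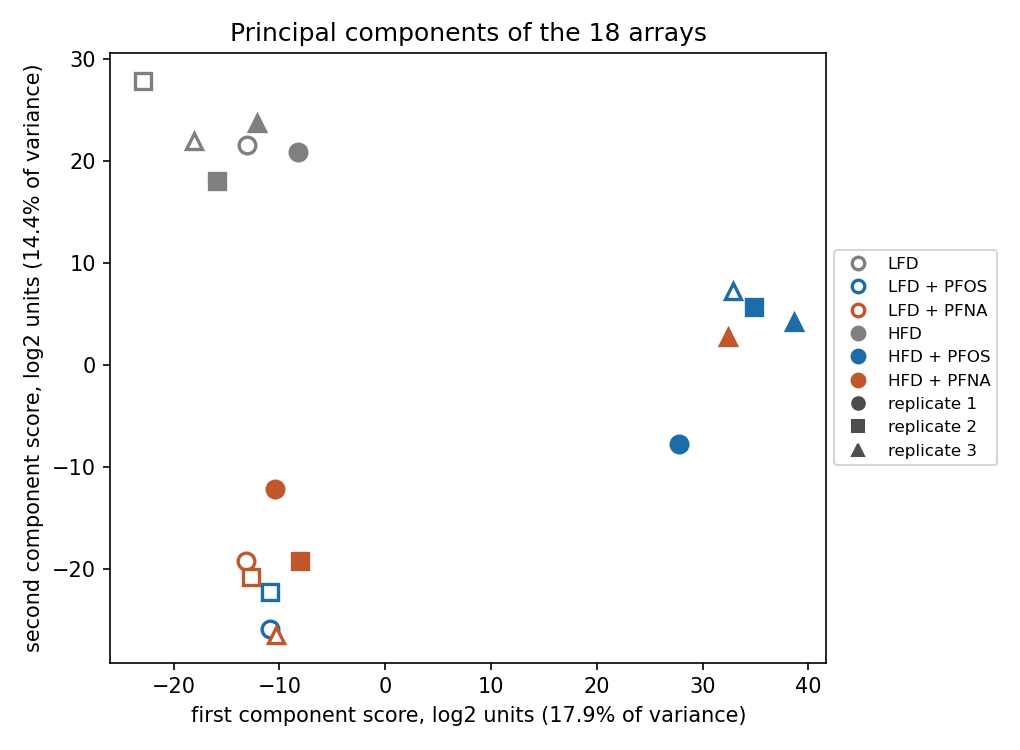
Scores of the 18 arrays on the first (horizontal axis) and second (vertical axis) principal component, in log2 units, with open symbols for the low-fat and filled symbols for the high-fat diet, colours for the compound and shapes for the replicate. The first component held 17.9% and the second 14.4% of the variance, and replicate 3 of PFOS on the low-fat diet (32.9) and of PFNA on the high-fat diet (32.4) lie beside the arrays of PFOS on the high-fat diet.

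**Figure D2:**
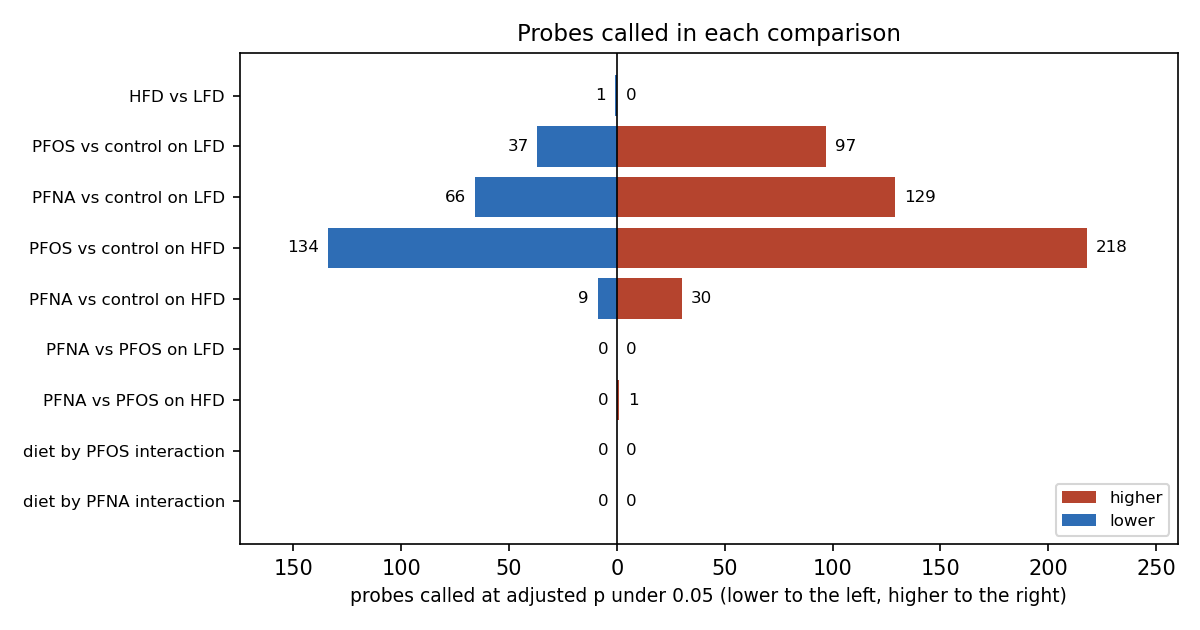
Number of probes called at an adjusted p under 0.05 in each of the 9 contrasts, with probes lower in the first group to the left and higher to the right of 0. PFOS on the high-fat diet gave the largest numbers, 218 higher and 134 lower, whereas the interactions of diet with each compound gave 0.

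The comparison of the 2 control groups asked what the high-fat diet did alone. Genes of cholesterol synthesis were higher on the high-fat diet as a list, with a mean log2 difference of 0.72 over 19 measured members (adjusted p = 8.54e-14; adjusted p = 0.133 with an estimated correlation). Sqle, which makes squalene epoxide, differed by 1.91 (SE 0.38, adjusted p = 0.288) and Msmo1, a later enzyme of the pathway, by 1.61 (SE 0.34, adjusted p = 0.313). Both were higher in 3 of 3 high-fat arrays than in any low-fat control. None of the 19 members was called over all probes, and 9 were higher when adjusted over the list alone. The acute phase list, of genes of the liver's response to inflammation, rose by a mean of 0.71 (adjusted p = 1.90e-10; adjusted p = 0.133 with an estimated correlation), with 4 of 19 members higher adjusted over the list alone. Its largest differences were in Lcn2 (2.17, SE 0.69, adjusted p = 0.679) and Saa2 (2.13, SE 0.84, adjusted p = 0.739).

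Lists of NRF2 targets (adjusted p = 1.11e-07, or adjusted p = 0.118 with an estimated correlation), endoplasmic reticulum stress (2.03e-06, or adjusted p = 0.209 with an estimated correlation) and cell cycle genes (2.02e-05, or adjusted p = 0.209 with an estimated correlation) were also higher on the high-fat diet. So were the transporters of foreign compounds (adjusted p = 0.00593, or adjusted p = 0.133 with an estimated correlation), whose mean was 0.31 and whose median was 0.00. Among markers of other cells, those of stellate cells and fibrosis rose (adjusted p = 1.65e-08, or adjusted p = 0.151 with an estimated correlation), as did those of lymphocytes (6.77e-04, or adjusted p = 0.133 with an estimated correlation). The largest fibrosis differences were in Col3a1 (1.12, SE 0.35, adjusted p = 0.635) and Col1a1 (1.06, SE 0.35, adjusted p = 0.679), fibrillar collagens. Col1a1 reached 8.41 in high-fat control replicate 1 and was 6.22 and 6.85 in replicates 2 and 3. The list of the urea cycle and amino acid catabolism fell (adjusted p = 2.22e-04, or adjusted p = 0.364 with an estimated correlation), with Got1 at −1.21 (SE 0.32) and Agxt at −0.67 (SE 0.14).

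The other 5 list calls between the diets ended without a single array. The male-predominant genes, lower as a list (adjusted p = 1.53e-04, or adjusted p = 0.252 with an estimated correlation), lost the call without low-fat replicate 1 (0.0506). The Kupffer cell markers (adjusted p = 2.22e-04, or adjusted p = 0.481 with an estimated correlation) lost it without high-fat replicate 1 (0.441). The endothelial markers (adjusted p = 0.00390, or adjusted p = 0.546 with an estimated correlation) lost it without low-fat replicate 2 or high-fat replicate 1 or 2, with a highest adjusted p of 0.218 without high-fat replicate 1. The immediate-early genes (adjusted p = 0.00354, or adjusted p = 0.252 with an estimated correlation) lost it without low-fat replicate 2 (0.105) or high-fat replicate 1. The interferon-stimulated genes (adjusted p = 0.0407, or adjusted p = 0.630 with an estimated correlation) lost it without low-fat replicate 1 (0.966) or 2 or high-fat replicate 1 or 2.

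Across all probes, limma called 1 for the diet, 5730420D15Rik, which was lower, at −1.10 (SE 0.15, adjusted p = 0.0295) and is named because it was the single call. At an unadjusted p under 0.05 there were 2222 probes, where 1724 are expected by chance. The count was 0 without low-fat replicate 1, without low-fat replicate 2 and without high-fat replicate 3. It was 3 without low-fat replicate 3 and 2 without high-fat replicate 1 or replicate 2, and the call of 5730420D15Rik itself also ended without high-fat replicate 2 (adjusted p = 0.0819). The count was 0 without the 2 divergent arrays.

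On the low-fat diet, PFOS raised single genes whose products act on foreign compounds. Cyp2b10, the classic target of the nuclear receptor CAR (probe 17475360), rose by 5.20 (SE 0.67, adjusted p = 0.00391), from a signal between 3.81 and 4.58 in the 3 controls to between 7.94 and 10.63 in the 3 PFOS arrays. The control signal lay near the median of all probes, so it is not shown to be above background. The size of the log2 difference of Cyp2b10, here and in the other exposures, is therefore of array signal and not a measured size of the change in RNA. No fold is given, and Cyp2c55 is treated alike, although its control signals are not given here. The rise of Cyp2b10 itself does not rest on that size, since its lowest signal in an exposed array was 7.26 and its highest in a control 4.58. Cyp2c55, another cytochrome P450, rose by 3.33 (SE 0.47, adjusted p = 0.00552). Gsta4, a glutathione transferase, rose by 1.30 (SE 0.14, adjusted p = 0.00115), and Abcc3, an efflux pump, rose by 0.90 (SE 0.13, adjusted p = 0.00645). Among the falls was Cyp17a1, a steroid hydroxylase, at −1.86 (SE 0.31, adjusted p = 0.0145).

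The CAR and PXR list rose under PFOS on the low-fat diet (adjusted p = 2.60e-14; adjusted p = 0.0628 with an estimated correlation). Of its 24 measured members 7 rose, 0 fell and 17 did not pass, and 12 were higher adjusted over the list alone. Its called members included Gstm3 (3.26, SE 0.65) and Cyp2b9 (2.52, SE 0.42). The NRF2 list of genes for antioxidant defence rose (adjusted p = 2.26e-11; adjusted p = 0.0236 with an estimated correlation), with 5 of 20 members higher, among them Nqo1 (1.01, SE 0.20). At the preset correlation both list calls held without any 1 of the 6 arrays. With an estimated correlation the NRF2 call was lost when the 2 divergent arrays were left out (adjusted p = 0.0892). In the lipid droplet list 2 of 17 members rose, the lipases Pnpla2 (0.82, SE 0.13) and Lipe (0.57, SE 0.12), with a list adjusted p of 4.11e-05 and adjusted p = 0.401 with an estimated correlation. In the list of fatty acid and triglyceride synthesis 1 of 23 members rose, Mid1ip1 (1.26, SE 0.19), which activates acetyl-CoA carboxylase, with a list adjusted p of 9.64e-04 and adjusted p = 0.401 with an estimated correlation. Cholesterol synthesis rose as a list with 0 of 19 members called (adjusted p = 4.11e-05; adjusted p = 0.401 with an estimated correlation).

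Markers of other liver cells moved with PFOS on the low-fat diet without a single called member. The endothelial list rose (adjusted p = 1.25e-06), with Lyve1 at 1.08 (SE 0.30, adjusted p = 0.141), as did the Kupffer cell list (2.40e-05), with Cd68 at 1.07 (SE 0.31, adjusted p = 0.154), the fibrosis list (9.64e-04) and the cell cycle list (0.00127). Each of these 4 lists had an adjusted p = 0.401 with an estimated correlation. The same 4 lists, and those of NRF2 targets and cholesterol synthesis, were also called higher in the high-fat controls against these low-fat controls. Their tests do not separate a response from the level of the low-fat controls.

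Of the remaining calls for PFOS on the low-fat diet, 3 lists of fatty acid metabolism rested on its replicate 3, a divergent array. Peroxisomal oxidation (adjusted p = 0.00286, or adjusted p = 0.519 with an estimated correlation), mitochondrial oxidation (0.00286, or adjusted p = 0.519 with an estimated correlation) and other PPARA targets (9.64e-04, or adjusted p = 0.401 with an estimated correlation) were higher. Among their members Cd36, a fatty acid transporter, rose (1.47, SE 0.31, adjusted p = 0.0460). Ehhadh, a peroxisomal enzyme, read 13.17 in replicate 3 and 11.28 and 11.64 in replicates 1 and 2. Without replicate 3 the adjusted p of these 3 lists was 0.495, 0.353 and 0.175. Oxidative phosphorylation (adjusted p = 0.0159, or adjusted p = 0.602 with an estimated correlation) and the adipocyte markers (0.0319, or adjusted p = 0.285 with an estimated correlation) also rose, and complement and coagulation fell (0.0330, or adjusted p = 0.623 with an estimated correlation). These calls ended without replicate 3 (0.697, 0.165 and 0.954), the last of them with its direction turned. All 3 also ended without low-fat control replicate 3, and the last 2 without low-fat control replicate 1.

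In all, 134 probes were called for PFOS on the low-fat diet, 97 higher and 37 lower, of which 30 had no gene assigned. Quantile normalization gave 53 higher and 32 lower, and a fit to the 2 compared groups alone gave 6 calls in all. The count was 48, 35 and 30 without low-fat control replicate 1, 2 or 3, and 22, 38 and 260 without PFOS replicate 1, 2 or 3. Leaving out the 2 divergent arrays gave 454 (264 higher, 190 lower), and 115 of the 134 were among them. The fit to the compared groups alone ended the calls of 26 of the 29 named genes. Of these 29, 8 held without any 1 array in the fit to all groups: Cyp2b10, Cyp2c55, Gsta4, Abcc3, Krt23, Slc35f2, Mid1ip1 and Cyp4a12a. The calls of 18, 17 and 19 named genes ended without control replicates 1, 2 and 3, and of 18, 14 and 14 without PFOS replicates 1, 2 and 3, with a highest adjusted p of 0.189.

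On the low-fat diet, PFNA raised single genes whose products act on foreign compounds. Cyp2b10 rose by 5.71 (SE 0.67, adjusted p = 0.00125) and was between 9.44 and 10.34 in the 3 PFNA arrays. Cyp2c55 rose by 3.72 (SE 0.47, adjusted p = 0.00196), Gstm3 by 3.79 (SE 0.65, adjusted p = 0.0128) and Gsta4 by 1.34 (SE 0.14, adjusted p = 5.36e-04). Cyp17a1 fell, at −2.12 (SE 0.31, adjusted p = 0.00614), and so did Ppargc1a, a coactivator of mitochondrial and gluconeogenic genes, at −1.10 (SE 0.20, adjusted p = 0.0163).

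Of the 24 CAR and PXR genes 7 rose and 0 fell under PFNA on the low-fat diet, and 14 were higher adjusted over the list alone (list adjusted p = 4.62e-18; adjusted p = 0.0279 with an estimated correlation). Of the 20 NRF2 genes 5 rose, among them Abcc3 (0.95, SE 0.13) and Nqo1 (0.91, SE 0.20), and 10 were higher adjusted over the list alone (list adjusted p = 3.48e-10; adjusted p = 0.0279 with an estimated correlation, and 0.0530 with it when the 2 divergent arrays were left out). The endothelial markers rose as a list (adjusted p = 5.80e-09; adjusted p = 0.232 with an estimated correlation). None of its 13 members was called over all probes and 11 were higher adjusted over the list alone, such as Lyve1 (1.23, SE 0.30) and Oit3 (0.96, SE 0.21). The cell cycle list rose (adjusted p = 5.14e-07; adjusted p = 0.188 with an estimated correlation), with 1 of 24 members called, the replication licensing factor Mcm2 (0.87, SE 0.18). Kupffer cell markers (adjusted p = 2.54e-05; adjusted p = 0.439 with an estimated correlation), adipocyte markers (0.00630; adjusted p = 0.0701 with an estimated correlation) and cholesterol synthesis (8.05e-04; adjusted p = 0.640 with an estimated correlation) were higher as lists. At the preset correlation these 7 calls held without any 1 of the 6 arrays. The NRF2, endothelial, cell cycle, Kupffer cell and cholesterol lists were also called higher in the high-fat controls against these low-fat controls. So were the fibrosis and transporter lists, given below. Their tests do not separate a response from the level of the low-fat controls.

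The other 5 list calls for PFNA on the low-fat diet were each lost without at least 1 array, and PFNA replicate 3 ended 4 of them. Female-predominant genes were higher as a list (adjusted p = 0.00653, or adjusted p = 0.228 with an estimated correlation; 0.0651 without PFNA replicate 3). Of its 14 members 2 rose and 1 fell. The fibrosis markers (0.00653, or adjusted p = 0.640 with an estimated correlation) had 0.0991 without PFNA replicate 3. Lipid droplet genes (0.0246, or adjusted p = 0.651 with an estimated correlation) had 0.0920 without PFNA replicate 3 and also lost the call without control replicate 2 or 3. The transporters (0.0473, or adjusted p = 0.232 with an estimated correlation) had 0.0991 without PFNA replicate 3 and kept the call only without PFNA replicate 2. Fatty acid and triglyceride synthesis (0.0412, or adjusted p = 0.868 with an estimated correlation) had 0.198 without PFNA replicate 2 and also lost it without control replicate 2 or 3. The other PPARA targets had a mean difference of 0.15 as a list (adjusted p = 0.579).

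PFNA on the low-fat diet gave 195 calls, 129 higher and 66 lower, of which 47 had no gene assigned. Quantile normalization gave 114 higher and 89 lower. The count was 63, 45 and 127 without low-fat control replicate 1, 2 or 3, and 86, 84 and 26 without PFNA replicate 1, 2 or 3. With the 2 divergent arrays left out, neither of which is in this comparison but both of which enter the shared variance, 593 probes were called (383 higher, 210 lower), all 195 among them. A fit to the 2 compared groups alone gave 194 calls and ended those of 13 of the 29 named genes. Of these 29, 6 held without any 1 array in the fit to all groups: Cyp2b10, Cyp2c55, Gsta4, Abcc3, Cyp4a12a and Cyp17a1. The calls of 21, 16 and 12 ended without control replicates 1, 2 and 3, and of 13, 13 and 23 without PFNA replicates 1, 2 and 3, with a highest adjusted p of 0.215.

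On the high-fat diet, PFOS raised single genes of lipid metabolism together with Cyp2b10. Sptlc3, a subunit of the enzyme that starts sphingolipid synthesis, rose by 5.32 (SE 1.20, adjusted p = 0.0424), from between 3.71 and 4.30 in the controls to between 8.88 and 9.61. As its control signal lay below the median of all probes, the size of this rise is of array signal and not a measured size of the change in RNA. Cyp2b10 rose by 4.39 (SE 0.67, adjusted p = 0.00621). Acot1 (2.71, SE 0.37, adjusted p = 0.00218) and Acot2 (2.61, SE 0.43, adjusted p = 0.00935), acyl-CoA thioesterases, rose, as did Mogat1, which makes diacylglycerol (3.03, SE 0.49, adjusted p = 0.00935). Among the falls were Hsd3b5, a male-specific steroid dehydrogenase of the liver, at −4.99 (SE 0.99, adjusted p = 0.0255), and the uptake transporters Slco1a1 at −3.87 (SE 0.65, adjusted p = 0.00936), Slc22a7 at −1.95 (SE 0.43) and Slc22a30 at −1.78 (SE 0.19, adjusted p = 1.76e-04). The PFOS signals of Hsd3b5 (2.39 to 2.96) and Slc22a30 (3.93 to 4.58) lay near or below the median of all probes, so the size of these falls is limited by a level not shown to be above background.

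In the peroxisomal list 5 of 19 members rose, among them Ehhadh (1.98, SE 0.40, adjusted p = 0.0259) and Crat (1.09, SE 0.18), and 12 were higher adjusted over the list alone (list adjusted p = 1.88e-13; adjusted p = 0.112 with an estimated correlation). In the mitochondrial list 3 of 19 rose, among them Acadl (0.73, SE 0.15) and Slc25a20 (0.63, SE 0.13), and 13 adjusted over the list alone (list adjusted p = 3.42e-12; adjusted p = 0.112 with an estimated correlation). Of 16 other PPARA targets 4 rose, among them Cyp4a31 (2.47, SE 0.50), and 11 adjusted over the list alone (list adjusted p = 1.17e-11; adjusted p = 0.112 with an estimated correlation). Oxidative phosphorylation rose as a list with 0 of 22 members called (3.35e-09; adjusted p = 0.131 with an estimated correlation). Of 17 lipid droplet genes 4 rose, among them Hsd17b11 (1.74, SE 0.28), Pnpla2 (1.19, SE 0.13) and Lipe (0.86, SE 0.12), with a list adjusted p of 3.88e-12 and adjusted p = 0.112 with an estimated correlation. Of 23 genes of fatty acid and triglyceride synthesis 5 rose, among them Acacb (1.84, SE 0.40), Me1 (1.59, SE 0.36) and the lipogenic regulator Srebf1 (1.27, SE 0.24), with a list adjusted p of 2.08e-08 and adjusted p = 0.129 with an estimated correlation.

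CAR and PXR genes (2 of 24 higher, list adjusted p = 0.00320, or adjusted p = 0.304 with an estimated correlation), NRF2 genes (2 of 20 higher, 1.71e-04, or adjusted p = 0.112 with an estimated correlation) and cell cycle genes (0 of 24 called, 0.00115, or adjusted p = 0.214 with an estimated correlation) were higher as lists under PFOS on the high-fat diet. The NRF2 members that rose were Abcc4 (1.65, SE 0.34) and Ephx1 (0.54, SE 0.12). Cholesterol synthesis (0 of 19 called, 0.0190, or adjusted p = 0.524 with an estimated correlation) was higher as a list, and the call ended with its direction turned without PFOS replicate 1 (0.637). The adipocyte markers (1 of 8 higher, 0.0274, or adjusted p = 0.112 with an estimated correlation) lost their call without high-fat control replicate 3 (0.0810) or PFOS replicate 1.

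Several lists fell under PFOS on the high-fat diet. Complement and coagulation (adjusted p = 3.42e-12; adjusted p = 0.112 with an estimated correlation) had 1 of 26 members lower, the lectin Mbl1 (−0.68, SE 0.16), and 12 adjusted over the list alone. The acute phase list (6.17e-07; adjusted p = 0.131 with an estimated correlation) had 1 of 19 lower, Steap4 (−1.39, SE 0.24). None of 16 interferon-stimulated genes was called over all probes and 12 were lower adjusted over the list alone, such as Ifit1 (−1.61, SE 0.38) and Mx2 (−1.24, SE 0.30), with a list adjusted p of 2.55e-10 and adjusted p = 0.112 with an estimated correlation. Endoplasmic reticulum stress fell as a list (3.42e-06; adjusted p = 0.133 with an estimated correlation), with Herpud1 called (−0.72, SE 0.15), as did immediate-early genes (0.00387; adjusted p = 0.174 with an estimated correlation), with Egr1 called (−1.18, SE 0.23). These 2 lists and the acute phase and interferon lists were called higher in the high-fat than in the low-fat controls. So were the transporter, fibrosis and lymphocyte lists, given below. Acute phase means were 9.7, 10.24 and 9.73 in the high-fat and 8.94, 9.22 and 9.38 in the low-fat controls. With PFOS on the high-fat diet they were 8.78, 9.09 and 9.57. The tests of these lists do not separate a response from the level of the high-fat controls.

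Pericentral genes, which mark hepatocytes around the central vein, fell with 3 of 12 members lower, Gulo (−1.38, SE 0.32), Lgr5 (−1.22, SE 0.23) and Slc1a2 (−0.87, SE 0.19), with a list adjusted p of 2.34e-04 and adjusted p = 0.208 with an estimated correlation. The bile acid list (1 of 20 lower, 6.67e-05, or adjusted p = 0.112 with an estimated correlation) and the transporter list (2 higher and 3 lower of 15, 0.0114, or adjusted p = 0.112 with an estimated correlation) fell under PFOS on the high-fat diet.

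Male-predominant genes had 3 members higher and 4 lower of 15, with a list adjusted p of 0.0476 and adjusted p = 0.467 with an estimated correlation. This call for PFOS on the high-fat diet ended without control replicate 2 or 3 or PFOS replicate 2 or 3 (highest 0.193, without PFOS replicate 3). Circadian genes (0.0392, or adjusted p = 0.449 with an estimated correlation) were lower as a list and lost the call without control replicate 1 or 2 (0.193 without replicate 2) or PFOS replicate 2 or 3. Fibrosis markers (7.18e-04, or adjusted p = 0.272 with an estimated correlation) were lower and lost it without control replicate 1 (0.324). Lymphocyte markers (0.0325, or adjusted p = 0.173 with an estimated correlation) were lower and lost it without control replicate 1 (0.125) or PFOS replicate 3. Exocrine pancreas markers (0.0272, or adjusted p = 0.131 with an estimated correlation) were lower and lost it without control replicate 2 (0.181) or PFOS replicate 3. The calls of 17 of the 24 lists that passed held without any 1 of the 6 arrays.

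PFOS on the high-fat diet gave 352 calls, 218 higher and 134 lower, of which 59 had no gene assigned. The count was 184, 93 and 82 without high-fat control replicate 1, 2 or 3, and 157, 61 and 118 without PFOS replicate 1, 2 or 3. Without the 2 divergent arrays, neither of which is in this comparison, 1011 probes were called (621 higher, 390 lower), all 352 among them. A fit to the 2 compared groups alone gave 283 calls and ended those of 8 of the 48 named genes. Of these 48, 11 held without any 1 array in the fit to all groups: Acot1, Acot2, Acot3, Crat, Ctse, Cyp2b10, Krt23, Lipe, Mogat1, Pnpla2 and Slc22a30. The calls of 21, 32 and 34 named genes ended without control replicates 1, 2 and 3, and of 23, 35 and 29 without PFOS replicates 1, 2 and 3, with a highest adjusted p of 0.186. Ehhadh, Sptlc3 and Hsd3b5 lost theirs without any of the 6, with highest adjusted p of 0.0903, 0.133 and 0.0869.

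**Figure D3:**
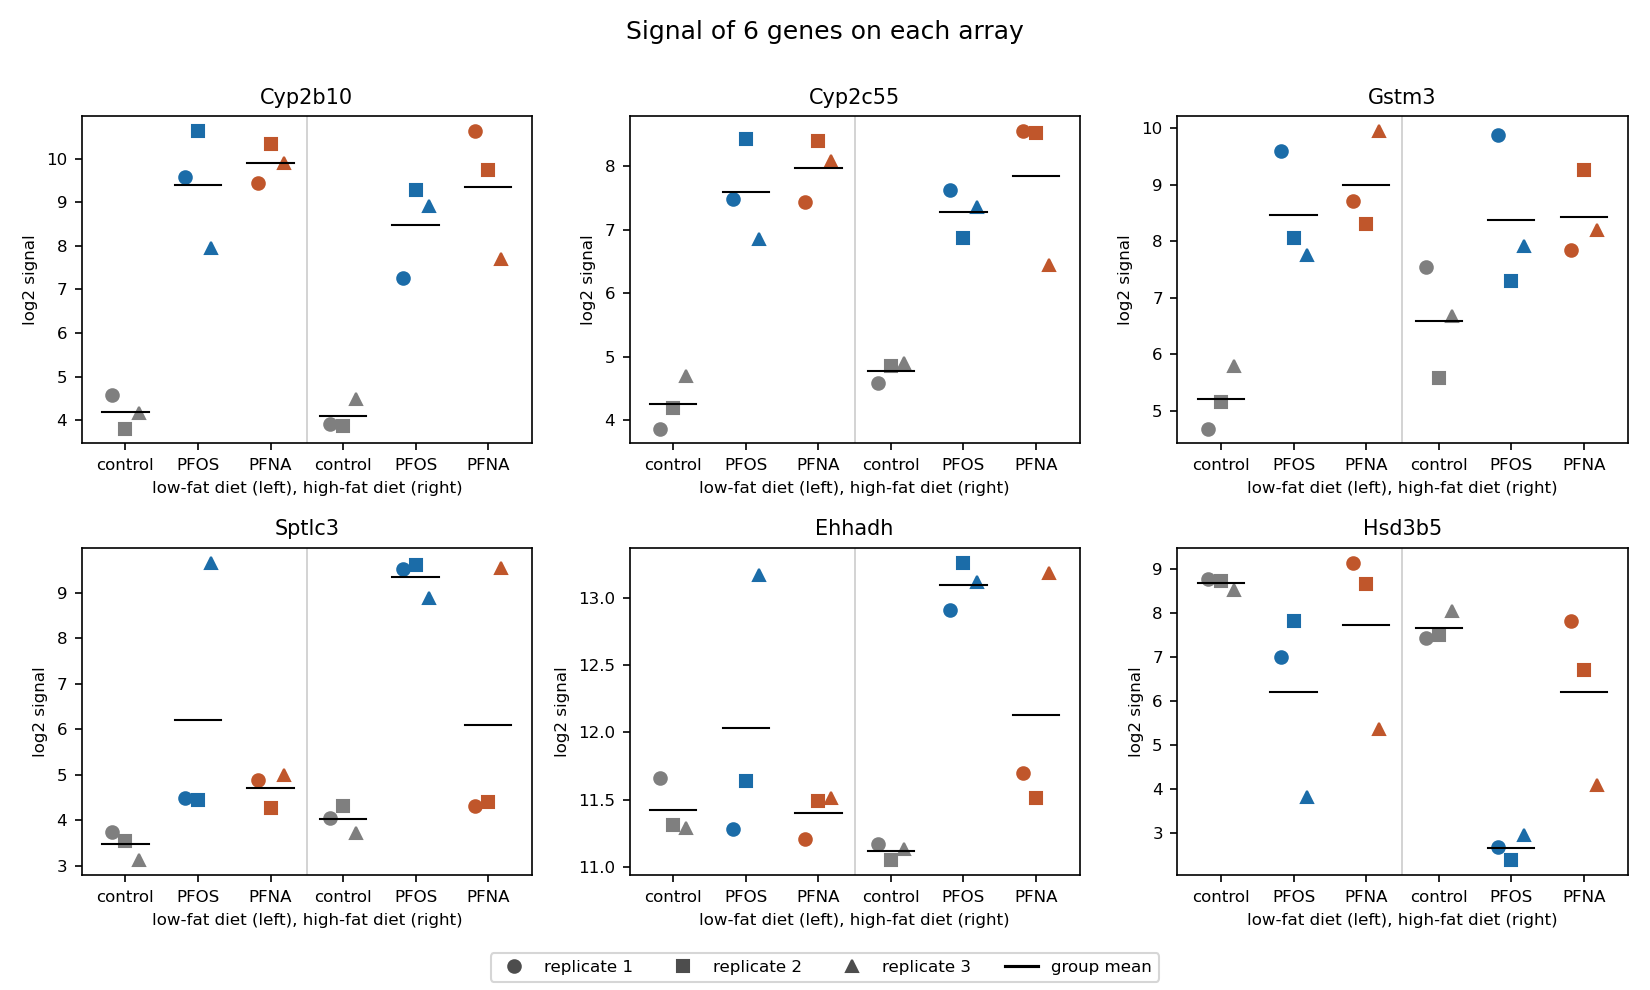
Log2 signal (vertical axis) of 6 genes on each of the 18 arrays, by group (horizontal axis), with shapes for the replicate and a line at each group mean. Cyp2b10 lies between 3.81 and 4.58 in the controls and between 7.26 and 10.63 in the exposed groups, whereas Sptlc3 is between 8.88 and 9.66 in the 3 arrays of PFOS on the high-fat diet and in replicate 3 of PFOS on the low-fat and PFNA on the high-fat diet, and between 4.27 and 5.0 in the other exposed arrays.

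On the high-fat diet, PFNA raised Cyp2b10 by 5.26 (SE 0.67, adjusted p = 0.00193) and Cyp2c55 by 3.06 (SE 0.47, adjusted p = 0.0103). Cyp4a12a (1.33, SE 0.14, adjusted p = 3.35e-04) and Cyp4a12b (2.05, SE 0.19, adjusted p = 1.17e-04), fatty acid hydroxylases of male liver and kidney, rose. So did Krt23, a keratin (2.34, SE 0.29, adjusted p = 0.00171), and Alpl, an alkaline phosphatase (1.37, SE 0.16, adjusted p = 0.00119). Among the falls was Igtp, an interferon-inducible GTPase, at −0.89 (SE 0.17, adjusted p = 0.0439).

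Of 24 CAR and PXR genes 3 rose and 0 fell under PFNA on the high-fat diet, and 11 were higher adjusted over the list alone (list adjusted p = 9.80e-12; adjusted p = 0.236 with an estimated correlation). The acute phase list fell (6.66e-08; adjusted p = 0.254 with an estimated correlation), with 0 of 19 members called and Saa2 at −1.69 (SE 0.84, adjusted p = 0.534). Endoplasmic reticulum stress (9.43e-06; adjusted p = 0.312 with an estimated correlation), interferon-stimulated genes (5.57e-05; adjusted p = 0.411 with an estimated correlation) and complement and coagulation (1.08e-04; adjusted p = 0.411 with an estimated correlation) were lower as lists, each with 0 called members. These 5 calls held without any 1 of the 6 arrays. The acute phase, endoplasmic reticulum stress and interferon lists were called higher in the same high-fat controls against the low-fat controls. So were the fibrosis, lymphocyte and immediate-early lists, given below. The tests of these lists do not separate a response from the level of the high-fat controls.

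List calls on lipid metabolism under PFNA on the high-fat diet rested on replicate 3, the other divergent array. Of 17 lipid droplet genes 2 rose, Pnpla2 (0.85, SE 0.13) and Lipe (0.79, SE 0.12), with a list adjusted p of 5.57e-05, adjusted p = 0.312 with an estimated correlation, and 0.0763 without replicate 3. Without both divergent arrays 2 of the 17 members were still called higher. Peroxisomal oxidation (5.99e-05, or adjusted p = 0.411 with an estimated correlation), mitochondrial oxidation (4.16e-04, or adjusted p = 0.429 with an estimated correlation), other PPARA targets (5.89e-04, or adjusted p = 0.411 with an estimated correlation) and oxidative phosphorylation (5.99e-05, or adjusted p = 0.411 with an estimated correlation) were higher as lists with 0 called members. Without replicate 3 their adjusted p was 0.144, 0.307, 0.307 and 0.140. NRF2 genes (0.0136, or adjusted p = 0.411 with an estimated correlation; 0.148 without replicate 3) were higher with 1 of 20 called, Gsta4 (0.79, SE 0.14), and also lost the call without control replicate 2. Fatty acid and triglyceride synthesis (0.00925, or adjusted p = 0.456 with an estimated correlation; 0.140 without replicate 3) also lost it without control replicate 3.

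The other 6 list calls for PFNA on the high-fat diet ended without several single arrays. Among them, the signals of the lymphocyte and pancreas lists are not shown to be above background, as said above. Fibrosis markers were lower (0.0136, or adjusted p = 0.456 with an estimated correlation; 0.940 without control replicate 1, and lost without PFNA replicate 3). Lymphocyte markers were lower (0.0120, or adjusted p = 0.254 with an estimated correlation; 0.0846 without PFNA replicate 3, and lost without control replicate 1). Exocrine pancreas markers were lower (0.00763, or adjusted p = 0.254 with an estimated correlation; 0.0999 without PFNA replicate 3, and lost without control replicate 2). Immediate-early genes were lower (0.0354, or adjusted p = 0.411 with an estimated correlation; 0.315 without PFNA replicate 2, and lost without control replicate 1 or 2). The urea cycle was higher (0.0354, or adjusted p = 0.529 with an estimated correlation; 0.499 without PFNA replicate 1, and lost without control replicate 1 or 3). Adipocyte markers were higher with 1 of 8 called (0.0430, or adjusted p = 0.254 with an estimated correlation; 0.144 without control replicate 3, and lost without control replicate 2 or PFNA replicate 2 or 3).

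PFNA on the high-fat diet gave 39 calls, 30 higher and 9 lower, of which 7 had no gene assigned. The count was 34, 21 and 24 without high-fat control replicate 1, 2 or 3, and 9, 15 and 31 without PFNA replicate 1, 2 or 3. Leaving out the 2 divergent arrays gave 148 (104 higher, 44 lower), and 32 of the 39 were among them. A fit to the 2 compared groups alone gave 6 calls and ended those of 15 of the 17 named genes, whereas the variance trend gave 120 and the brighter probes 115. Of these 17, 7 held without any 1 array in the fit to all groups: Alpl, Cyp2b10, Cyp4a12a, Cyp4a12b, Krt23, Slc35f2 and Sulf2. The calls of 5, 8 and 8 ended without control replicates 1, 2 and 3, and of 10, 9 and 4 without PFNA replicates 1, 2 and 3, with a highest adjusted p of 0.166.

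**Figure D4:**
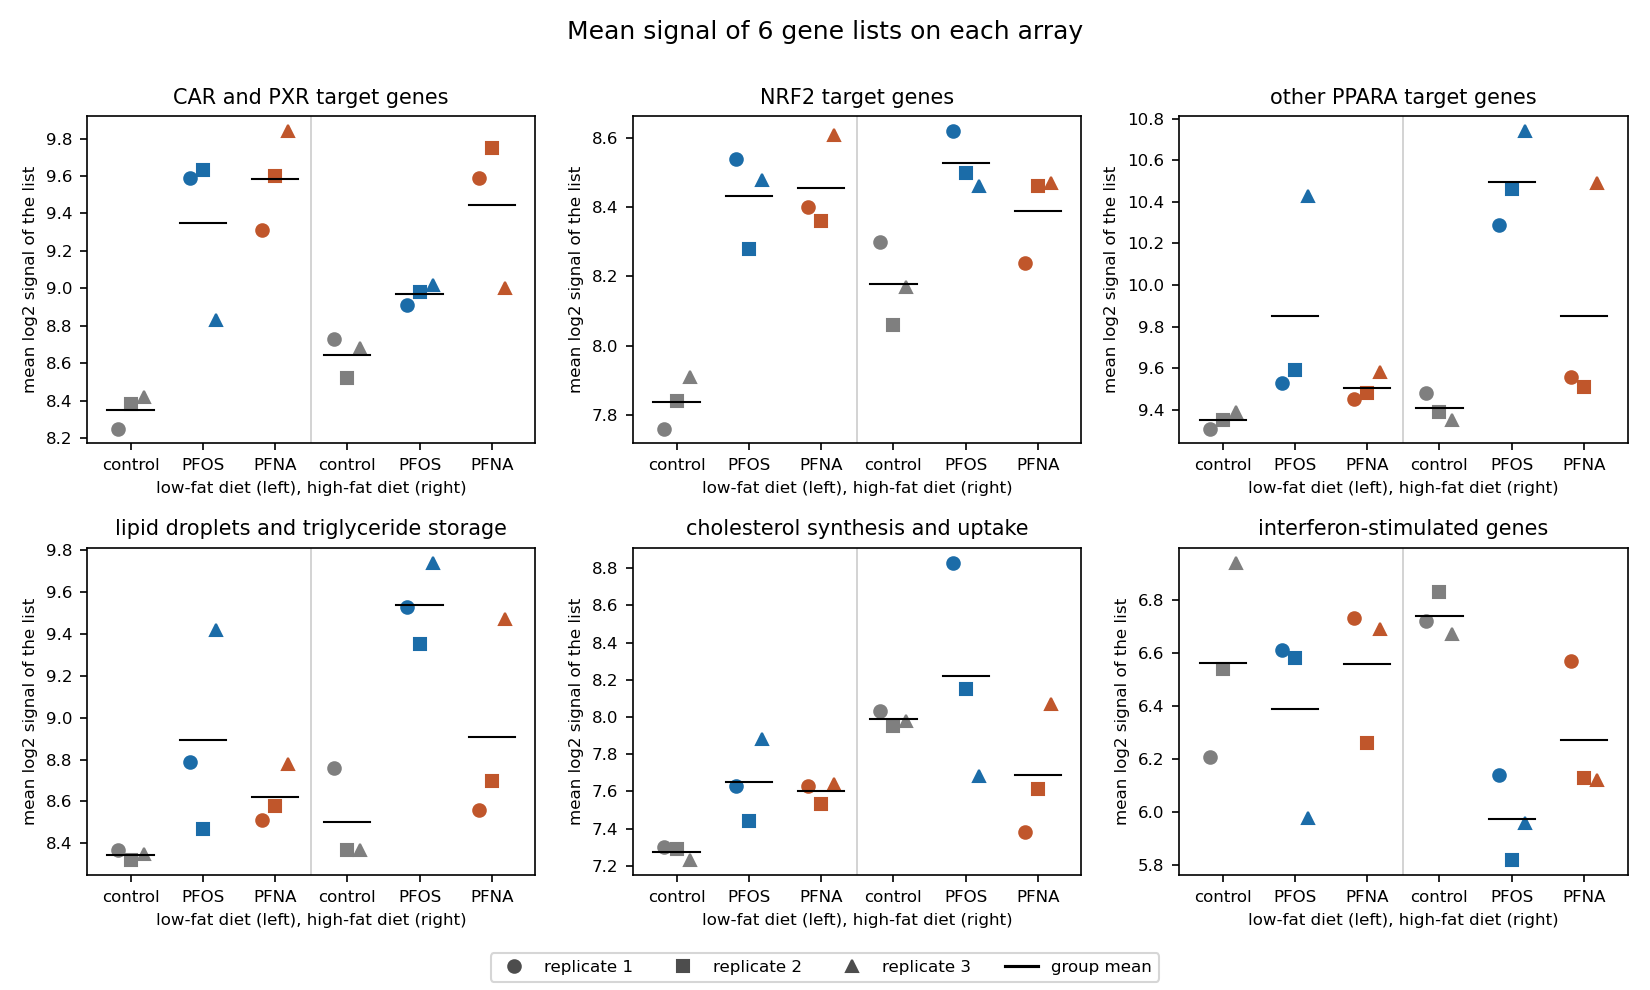
Mean log2 signal (vertical axis) of 6 gene lists on each of the 18 arrays, by group (horizontal axis), with shapes for the replicate and a line at each group mean. The mean of the other PPARA targets is 10.43 in replicate 3 of PFOS on the low-fat diet and 10.49 in replicate 3 of PFNA on the high-fat diet, beside 10.29, 10.46 and 10.74 for PFOS on the high-fat diet, while their CAR and PXR means are 8.83 and 9.0.

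The 2 divergent arrays stood apart from their groups in these same lists. Each was the array most correlated with the other (r = 0.9895). With the arrays of its own group the highest correlation was 0.9831 for the PFOS array and 0.9846 for the PFNA array. The mean of the PPARA targets was 9.53 and 9.59 in replicates 1 and 2 of PFOS on the low-fat diet and 10.43 in replicate 3. It was 9.56 and 9.51 in replicates 1 and 2 of PFNA on the high-fat diet and 10.49 in replicate 3. The CAR and PXR mean was 9.59, 9.63 and 8.83 in the former group and 9.59, 9.75 and 9.0 in the latter, and 8.91, 8.98 and 9.02 in the arrays of PFOS on the high-fat diet. Without the 2 divergent arrays, the PPARA list had an adjusted p of 0.0980 for PFOS on the low-fat diet and 0.194 for PFNA on the high-fat diet. The CAR and PXR list then passed with an estimated correlation for PFOS on the low-fat diet (adjusted p = 0.00111), PFNA on the low-fat diet (0.00121) and PFNA on the high-fat diet (0.00272). The peroxisomal (0.00243), mitochondrial (0.0244), other PPARA (0.00127) and lipid droplet (0.00887) lists then passed with an estimated correlation for PFOS on the high-fat diet. So did 6 more lists of that contrast, bile acids, transporters, complement and coagulation, oxidative phosphorylation and adipocyte markers (each 0.0480) and pericentral genes (0.0498). The NRF2 list, which had passed on the low-fat diet with all arrays, then did not pass with an estimated correlation for PFOS (0.0892) or PFNA (0.0530).

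The comparison of PFNA with PFOS within a diet asked whether the change of head group went with a change of response, at doses that are not given. On the low-fat diet limma called 0 of the 34472 probes, with 1351 at an unadjusted p under 0.05 and a smallest adjusted p of 0.998. Cyp2b10 rose under both compounds, and of the CAR and PXR genes the differences with the largest size were in Slco1a4 (1.54, 95% CI −0.39 to 3.46) and Cyp2b13 (1.36, 95% CI −0.75 to 3.48). In 6 lists PFNA and PFOS differed at the preset correlation. The lists of peroxisomal oxidation (adjusted p = 6.07e-04), mitochondrial oxidation (0.00180) and other PPARA targets (0.00180) were lower with PFNA, and those of bile acids (0.0413), pericentral genes (1.46e-05) and cell cycle (0.0389) were higher. Each had adjusted p = 0.887 with an estimated correlation. All 6 calls ended without PFOS replicate 3, with adjusted p of 0.729, 0.687, 0.740, 0.854 and 0.543 for the first 5. Mitochondrial oxidation was also lost without PFNA replicate 1, bile acids without PFNA replicate 1 or 2, and cell cycle without PFOS replicate 2 or PFNA replicate 3 (0.724). The count stayed at 0 without the 2 divergent arrays. The acute phase list was then lower with PFNA at the preset correlation (adjusted p = 0.00543; adjusted p = 0.938 with an estimated correlation).

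On the high-fat diet 1 probe differed between the compounds, Slc22a30 (probe 17362430), an organic anion transporter. It was higher with PFNA by 1.36 (SE 0.19, 95% CI 0.96 to 1.75, adjusted p = 0.0472), at 5.45 to 5.89 in the 3 PFNA and 3.93 to 4.58 in the 3 PFOS arrays. The PFOS signal lay near the median of all probes and is not shown to be above background, so the difference and its interval are of array signal alone. There were 2501 probes at an unadjusted p under 0.05. Each of the 6 arrays ended the call of Slc22a30 when left out. Its adjusted p was 0.0646, 0.484 and 0.0746 without PFNA replicate 1, 2 or 3 and 0.0775, 0.376 and 0.119 without PFOS replicate 1, 2 or 3. The count was 0 in 5 of these and 1, another probe, without PFNA replicate 3. With the 2 divergent arrays left out, 510 probes differed (259 higher, 251 lower with PFNA). Of these arrays PFNA replicate 3 is in this comparison and had lain beside the PFOS arrays, so its removal favours a larger count.

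Lists of lipid metabolism were lower with PFNA than with PFOS on the high-fat diet. They were peroxisomal oxidation (adjusted p = 2.57e-07; adjusted p = 0.305 with an estimated correlation), mitochondrial oxidation and other PPARA targets (each 4.25e-07; adjusted p = 0.305 with an estimated correlation) and lipid droplets (6.58e-06; adjusted p = 0.305 with an estimated correlation). Among their members Pdk4 differed by −2.33 (95% CI −4.04 to −0.62) and Cidea by −3.73 (95% CI −6.86 to −0.60), which were −3.54 and −5.58 without the 2 divergent arrays, of which PFNA replicate 3 is the one in this comparison. CAR and PXR genes (2.37e-05; adjusted p = 0.305 with an estimated correlation), complement and coagulation (1.52e-05; adjusted p = 0.330 with an estimated correlation) and pericentral genes (1.52e-05; adjusted p = 0.305 with an estimated correlation) were higher with PFNA. These 7 calls held without any 1 of the 6 arrays. Without the 2 divergent arrays 6 of these 7 passed with an estimated correlation, at adjusted p of 0.00587, 0.0367, 0.00216, 0.0261, 0.0140 and 0.0367, and complement and coagulation did not (0.177). Circadian genes also passed then (0.0487). PFNA replicate 3 was left out because it lay beside the PFOS arrays on the first principal component. Its removal favours larger differences between the compounds, so these passes are not independent evidence.

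The other 8 list differences between the compounds on the high-fat diet each ended without at least 1 array. Lower with PFNA were fatty acid and triglyceride synthesis (2.48e-05, or adjusted p = 0.327 with an estimated correlation; 0.689 without PFOS replicate 1), cholesterol synthesis (4.25e-07, or adjusted p = 0.305 with an estimated correlation; 0.178 without PFOS replicate 1), cell cycle (3.91e-04, or adjusted p = 0.305 with an estimated correlation; 0.0709 without PFOS replicate 1) and oxidative phosphorylation (0.0126, or adjusted p = 0.685 with an estimated correlation; 0.366 without PFNA replicate 1). Cell cycle was also lost without PFNA replicate 1, and oxidative phosphorylation without PFOS replicate 1 or PFNA replicate 2. Higher with PFNA were bile acids (4.16e-04, or adjusted p = 0.305 with an estimated correlation; 0.0926 without PFOS replicate 3), male-predominant genes (0.0279, or adjusted p = 0.560 with an estimated correlation; 0.183 without PFOS replicate 3), interferon-stimulated genes (4.68e-04, or adjusted p = 0.439 with an estimated correlation; 0.0741 without PFNA replicate 1) and circadian genes (0.00443, or adjusted p = 0.383 with an estimated correlation; 0.142 without PFNA replicate 2). Male-predominant genes were also lost without PFNA replicate 1 or 3, and circadian genes without PFNA replicate 1.

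The interaction tests asked whether the diet altered the response to a compound. For PFOS limma called 0 probes, with 2192 at an unadjusted p under 0.05 and a smallest adjusted p of 0.524. Acot1 had an interaction of 1.69 (95% CI 0.59 to 2.79, adjusted p = 0.759) and Cyp2b9 of −2.30 (95% CI −3.54 to −1.06, adjusted p = 0.664). For PFNA limma called 0, with 1786 at an unadjusted p under 0.05 and a smallest adjusted p of 0.938. Sqle had an interaction of −1.74 (95% CI −2.88 to −0.60, adjusted p = 0.942). When the 2 divergent arrays were left out, 83 probes passed for PFOS (45 higher, 38 lower) and 0 for PFNA. At the preset correlation 21 of the 36 lists passed for PFOS and 20 for PFNA, of which 16 and 11 held without any 1 array. With an estimated correlation 0 passed for either compound. With the 2 divergent arrays left out, 4 lists passed with an estimated correlation for PFOS, namely peroxisomal oxidation, other PPARA targets and CAR and PXR targets (each adjusted p = 0.00824) and transporters (0.00835), and 0 for PFNA. These lists are given in the closing section. Genes called on 1 diet and not on the other are therefore not shown to differ between diets.

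The calls of the 2 compounds overlapped. On the low-fat diet 88 probes were called for both in the same direction, 61 higher and 27 lower, and 0 in opposite directions. Independent lists of these sizes would share 0.43. Simulations with shared controls and no effects gave 0.01. As they leave little to be called in either contrast, this value is no reference for lists of these sizes. The log2 differences of all probes correlated at 0.744, where the shared controls alone gave 0.5, and the covariance exceeded the simulated one by 0.037. On the high-fat diet 34 probes were shared, 26 higher and 8 lower, against 0.22 and 0 by the same reckonings. The simulated 0 has the same limit. The correlation was 0.666, with 0.501 simulated, and the covariance exceeded the simulated one by 0.031. Across diets, which share no arrays, PFOS had 52 probes in common (44 higher, 8 lower; 0.76 for independent lists; r = 0.400) and PFNA 22 (18 higher, 4 lower; 0.13 for independent lists; r = 0.379). Each of the 4 overlaps had 0 probes in opposite directions. The 4 overlaps without the 2 divergent arrays were 308, 63, 108 and 104, and leaving out single arrays gave 19 to 155, 9 to 28, 16 to 72 and 9 to 22. The overlap of 88 was 155 without PFOS replicate 3 and 19 without PFOS replicate 1, that of 34 was 9 without PFNA replicate 1, that of 52 was 16 without low-fat control replicate 3, and that of 22 was 9 without PFNA replicate 1 of the high-fat diet. The 2 contrasts within a diet share their 3 controls, which cannot be split, so part of the excess may come from them.

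The size of the responses was compared over the 535 probes called in any of the 4 exposure contrasts. Their median absolute log2 difference was 0.60 for PFOS and 0.54 for PFNA on the low-fat diet, and 0.78 for PFOS and 0.52 for PFNA on the high-fat diet, with a median SE of 0.18. Of the 535 probes 352 were called for PFOS on the high-fat diet, so their choice favours a larger median there. Over all probes the medians were 0.15, 0.15, 0.15 and 0.14 in the same order, with a median SE of 0.17. None of these medians was tested against another.

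In 8 of the 36 lists no contrast passed with all arrays. Their lowest adjusted p over the 9 contrasts was 0.0812 for AHR targets, 0.342 for lipoproteins and lipid transport, 0.132 for glucose metabolism, 0.279 for periportal genes, 0.0505 for p53 targets, 0.660 for neutrophil markers, 0.0606 for cholangiocyte markers and 0.593 for the 1 measured erythroid marker. With the 2 divergent arrays left out, periportal genes passed at the preset correlation between the compounds on the high-fat diet (0.0466; adjusted p = 0.278 with an estimated correlation) and in the PFOS interaction (0.0148; adjusted p = 0.161 with an estimated correlation), and the other 7 in 0 contrasts. Single members of 4 of them were called, such as Pltp, a phospholipid transfer protein, which rose under PFOS on the low-fat diet (1.56, SE 0.30) and on the high-fat diet (1.74, SE 0.30). Among the lists that passed, the mean, the median and the test had the same sign apart from the transporters in the comparison of the 2 control groups. Among those that did not pass, they differed in sign in 6 lists for PFOS and 10 for PFNA on the low-fat diet, 5 for PFOS and 6 for PFNA on the high-fat diet, and 2 for the diet itself.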

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

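The tests below of exchanged labels, a control sample, adipose tissue and scaling were chosen only after the result they address was seen, as were leaving out the 2 divergent arrays, leaving out single arrays for the lists and exchanging the high-fat labels, and the form of the adipose test was changed after its first value was seen.

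The difference between diets in the response to a compound was tested for each gene list with the interaction of the linear model, at the preset correlation. With an estimated correlation 0 lists passed for either compound. At the preset correlation 21 lists passed for PFOS, and each is given as the mean log2 interaction of its members. Higher on the high-fat diet were peroxisomal oxidation (0.425), mitochondrial oxidation (0.326), other PPARA targets (0.588), fatty acid and triglyceride synthesis (0.204), lipid droplets (0.490) and oxidative phosphorylation (0.184). Lower were CAR and PXR targets (−0.679), NRF2 targets (−0.246), bile acids (−0.354), transporters (−0.729), complement and coagulation (−0.290), acute phase (−0.840), pericentral genes (−0.338), endoplasmic reticulum stress (−0.402), interferon-stimulated genes (−0.596), circadian genes (−0.296), immediate-early genes (−0.335), fibrosis (−0.655), Kupffer cells (−0.592), lymphocytes (−0.308) and endothelium (−0.340).

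For PFNA 20 lists passed at the preset correlation. Higher on the high-fat diet were peroxisomal oxidation (0.272), mitochondrial oxidation (0.199), other PPARA targets (0.292), the urea cycle (0.199) and oxidative phosphorylation (0.144). Lower were CAR and PXR targets (−0.430), NRF2 targets (−0.411), cholesterol synthesis (−0.626), transporters (−0.588), complement and coagulation (−0.149), acute phase (−0.650), pericentral genes (−0.271), endoplasmic reticulum stress (−0.398), cell cycle (−0.338), interferon-stimulated genes (−0.463), immediate-early genes (−0.239), fibrosis (−0.539), Kupffer cells (−0.641), lymphocytes (−0.348) and endothelium (−0.403).

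With an estimated correlation 0 of the 36 lists passed in either interaction, the lowest adjusted p being 0.135 for PFOS and 0.117 for PFNA. Without the 2 divergent arrays, which were left out because of their values, 4 lists passed with an estimated correlation for PFOS, namely peroxisomal oxidation, other PPARA targets and CAR and PXR targets (each adjusted p = 0.00824) and transporters (0.00835), and 0 for PFNA. The controls of both diets enter the difference between diets and the interaction with opposite signs. A list that happened to be high in the 3 high-fat or low in the 3 low-fat controls thus shifts both. By arithmetic it is higher in the difference between diets and lower in the interaction. Of the 14 lists called between the diets, 13 were called in the opposite direction in the PFNA interaction and 10 in the PFOS interaction, and 0 in the same direction in either. All 12 lists higher in the high-fat controls were lower in the PFNA interaction, and 10 of them in the PFOS interaction. For these lists the tests do not separate a diet-dependent response from the level of either control group.

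For PFOS, single arrays ended 5 of these calls. They were fatty acid and triglyceride synthesis (adjusted p = 0.655 without high-fat PFOS replicate 1, and lost without low-fat control replicate 1 or 3, low-fat PFOS replicate 2 or high-fat control replicate 2 or 3), bile acids (0.271 without high-fat PFOS replicate 3, and lost without low-fat control replicate 3 or low-fat PFOS replicate 1 or 2), lipid droplets (0.0524 without low-fat PFOS replicate 2), pericentral genes (0.203 without low-fat PFOS replicate 1, and lost without low-fat control replicate 3, low-fat PFOS replicate 2 or high-fat PFOS replicate 3) and circadian genes (0.0636 without low-fat PFOS replicate 1, and lost without low-fat PFOS replicate 2 or high-fat control replicate 2).

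For PFNA, leaving out the divergent high-fat PFNA replicate 3 ended the calls of peroxisomal oxidation (0.274), mitochondrial oxidation (0.614), other PPARA targets (0.847), CAR and PXR targets (0.566), pericentral genes (0.274), oxidative phosphorylation (0.498) and complement. Complement and coagulation reached 0.289 without high-fat control replicate 2, the urea cycle 0.196 without high-fat PFNA replicate 1 and immediate-early genes 0.218 without high-fat PFNA replicate 2. Other arrays also ended 8 of these 9 calls, peroxisomal oxidation being the exception. Low-fat control replicate 1 ended mitochondrial oxidation, other PPARA targets, CAR and PXR targets, the urea cycle, pericentral genes and oxidative phosphorylation, replicate 2 immediate-early genes, and replicate 3 other PPARA targets and pericentral genes. Low-fat PFNA replicate 1 ended mitochondrial oxidation, other PPARA targets and complement, replicate 2 CAR and PXR targets and immediate-early genes, and replicate 3 CAR and PXR targets and pericentral genes. High-fat control replicate 1 ended other PPARA targets, CAR and PXR targets and immediate-early genes, replicate 2 oxidative phosphorylation and immediate-early genes, and replicate 3 other PPARA targets, the urea cycle and pericentral genes.

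Other splits of the same arrays were counted for each number of probes called. With 6 arrays there are 10 splits, the labelled one among them, too few for a share under 0.05. The diet gave 1 probe and the highest other split 2, and 3 of 10 splits gave as many. The 4 exposures gave 134, 195, 352 and 39, with highest other splits of 1, 1, 1 and 0, and 1 of 10 splits, the labelled one, gave as many in each. The other splits mix control and exposed arrays, which puts an exposure effect into their variance. Their low counts therefore say little about chance. PFNA against PFOS gave 1 on the high-fat diet (highest other 1; 3 of 10 as many). On the low-fat diet it gave 0 (highest other 1), which each of the 10 splits reaches by construction, so this count says nothing about chance. For the same reason the 100 splits drawn for each interaction, of which 100 reached the observed 0, say nothing about chance. Their highest other splits called 1282 probes for PFOS and 115 for PFNA. Exchanging control and exposed labels within the high-fat diet, which turns the interaction into the sum of the 2 exposure effects, called 1282 and 946. A split that calls many probes thus need only carry the exposure effects, and what raised the 115 for PFNA was not tested.

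PFOS on the low-fat diet, replicate 3, and PFNA on the high-fat diet, replicate 3, had means of the other PPARA targets 0.870 and 0.949 above their group mates. An exchange of labels among the 12 exposed arrays could not by itself make all 4 groups as alike as the control groups. Any assignment to 4 groups of 3 left a group with a range of at least 0.839, where the labels gave 0.976 and the control groups at most 0.133. This outcome followed from the number of exposed arrays already seen to stand apart, which does not fill whole groups of 3. An exchange together with another cause therefore stays open. A control sample under either label is argued against, since Cyp2b10 was at least 7.70 in both and at most 4.58 in the 6 controls, a gap of 3.12. Adipose tissue in these samples is argued against by 4 adipocyte markers taken as not made by hepatocytes, Adipoq, Lep, Retn and Plin1. Their median difference was 0.093 in the PFOS array and −0.288 in the PFNA array, while Cidea differed by 6.28 and 5.56. Fabp4 (2.865 and 2.325) and Cidec (2.15 and 2.13) are also on the adipocyte list, were not among these 4 and rose with Cidea. Scaling is argued against, since the differences of the PPARA targets were 0.866 and 0.926 after quantile normalization. A wrong label involving an outside sample, a preparation batch that the labels do not give, and a response of the individual animal stay open, and no biological explanation was tested.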

How the results depend on the processing

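Leaving out both divergent arrays, and leaving out each array in turn for the lists, were chosen after seeing the data. The counts are ordered as the diet, PFOS and PFNA on the low-fat diet, PFOS and PFNA on the high-fat diet, PFNA against PFOS on the low-fat and on the high-fat diet, and the PFOS and PFNA interactions. They were 1, 134, 195, 352, 39, 0, 1, 0 and 0 as reported. No called probe changed sign in any setting.

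Quantile normalization gave 2, 85, 203, 375, 45, 0, 0, 0 and 0. The replicate block gave 3, 114, 208, 414, 47, 0, 0, 0 and 0. A fit to the compared groups alone gave 8, 6, 194, 283, 6, 0, 0, 0 and 0. It has fewer arrays to estimate the variance, but this alone does not account for the pattern. Comparisons of 2 groups all keep the same number of arrays, yet PFNA on the low-fat diet went from 195 to 194. PFOS on the low-fat diet fell from 134 to 6 and PFNA on the high-fat diet from 39 to 6. Each of these 2 comparisons holds a divergent array. The brighter probes alone gave 2, 270, 591, 794, 115, 0, 1, 0 and 0, with fewer probes tested. Trend with robust moderation gave 2, 193, 388, 550, 120, 0, 1, 0 and 0. An unadjusted p under 0.05 with a 2-fold change gave 89, 193, 238, 386, 166, 27, 100, 236 and 197, without adjustment for the number of probes. Leaving out both divergent arrays gave 0, 454, 593, 1011, 148, 0, 510, 83 and 0. For quantile normalization, the replicate block, the fit to the compared groups, the trend and the removal of both divergent arrays, the cause was not tested.

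Leaving out each array in turn gave 0 to 3 for the diet, 22 to 260 and 26 to 127 for PFOS and PFNA on the low-fat diet, 61 to 184 and 9 to 34 on the high-fat diet, 0 to 0 and 0 to 1 between the compounds, and 0 to 0 in both interactions. An arm then has 2 arrays, which are assumed to vary like the other groups.

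The overlaps, in the order of the low-fat pair, the high-fat pair, PFOS and PFNA across diets, were 88, 34, 52 and 22. They were 194, 93, 115 and 68 among the brighter probes, 5, 5, 3 and 4 in a fit to the compared groups, 143, 85, 86 and 60 with trend, 119, 111, 103 and 52 with an unadjusted p, 308, 63, 108 and 104 without both divergent arrays, 67, 40, 39 and 22 after quantile normalization, and 86, 36, 49 and 26 with the replicate block. Single arrays left out gave 19 to 155, 9 to 28, 16 to 72 and 9 to 22.

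In 3 lists the direction turned. Complement and coagulation for PFOS on the low-fat diet (adjusted p = 0.0330) turned without both divergent arrays (0.923, and 0.968 with an estimated correlation), with single arrays left out giving 0.00167 to 0.954, the latter without PFOS replicate 3, and the other settings 0.00841 to 0.623. Cholesterol synthesis for PFOS on the high-fat diet had 1.59e-07 to 0.637 with single arrays left out, and turned without PFOS replicate 1. Fatty acid and triglyceride synthesis in the PFOS interaction had 6.72e-04 to 0.655, and turned without high-fat PFOS replicate 1. The cause was not tested.

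Of the 145 list calls, 137 were kept after quantile normalization, 143 with the replicate block, 117 among the brighter probes, 111 without both divergent arrays, 26 with fry and 3 with an estimated correlation. In the same order these settings added 8, 5, 2, 10, 1 and 0 list calls. With an estimated correlation and without both divergent arrays, 24 passed. Of the 125 calls of named genes, 114 were kept after quantile normalization, 111 with the replicate block, 114 with trend, 119 without both divergent arrays and 123 of 123 among the brighter probes. A fit to the compared groups kept 61, among them 3 of 29 for PFOS and 16 of 29 for PFNA on the low-fat diet, and 40 of 48 and 2 of 17 on the high-fat diet.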

Other observations

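The genes below were counted, and the small nucleolar RNAs singled out, after their values were seen.

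In the 4 comparisons of a compound with its control, 17 probes were called each time, 15 higher and 2 lower in all 4. Of these 13 had 1 gene. Values follow the order PFOS and PFNA on the low-fat diet, then PFOS and PFNA on the high-fat diet. Beside Cyp2b10, Cyp2c55, Krt23, Slc35f2, Cyp4a12a, Pnpla2 and Lipe they were Alpl (1.16, 0.98, 1.61 and 1.37), Sulf2, a sulfatase of heparan sulfate (0.90, 0.68, 1.53 and 1.35), the phospholipase Pla2g6 (0.93, 0.90, 1.14 and 1.19), the amine transporter Slc18a1 (1.37, 1.17, 1.26 and 0.89), the iron-sulfur protein Cisd3 (0.85, 0.84, 0.85 and 0.78) and Ptma, prothymosin alpha (−0.65, −0.65, −0.78 and −0.72). Pnpla2 and Lipe encode the lipases that act in turn on stored triglyceride. The 17 probes were not recounted with arrays left out, and the comparisons within a diet share their controls. A count over all 4 comparisons cannot exceed the overlap of PFNA across diets. That overlap was 22 with all arrays and 9 without PFNA replicate 1 of the high-fat diet.

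Small nucleolar RNAs, a class in which small Cajal body RNAs were counted, guide the modification of other RNAs and had 81 probes. Their median log2 difference was −0.58 for PFOS and −0.51 for PFNA on the low-fat diet, with 71 and 73 of 81 below 0. It was −0.14 and −0.18 on the high-fat diet, with 54 and 61 below 0, and −0.01 between the diets, with 43 below 0. Of the 81, 1 was called for PFOS on the low-fat diet and 0 in each of the other 4. By array, the median difference from the mean of the low-fat controls was −1.05, −1.02 and 0.23 in replicates 1 to 3 of PFOS on the low-fat diet and −0.46, −0.47 and −0.54 in those of PFNA. It was −0.55, −0.14 and 0.01 for PFOS and −0.28, −0.59 and 0.11 for PFNA on the high-fat diet, 0.03, −0.10 and −0.03 in the high-fat controls and −0.08, 0.11 and −0.05 in the low-fat controls.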
